A study of Drosophila melanogaster with 30 samples.

How the data were processed

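RNA was measured in 30 libraries of Drosophila melanogaster, 2 in each of 15 groups that combine tissue, sex and genotype. Per the labels, poly(A) RNA was isolated, libraries were made with the PrepX RNA-Seq kit, and both ends of the fragments were sequenced on an Illumina HiSeq instrument. The labels write the control genotypes as X^X and X^Y, a notation commonly used for attached chromosomes that they do not spell out; the groups are called XX and XY here. Per the submitters' processing notes, Trim Galore, Bowtie2 and SAMtools were used, without a statement of their versions, and DESeq2 1.8.1 with R 3.2.3. The genome build and the strandedness of the libraries are not given in the sources used here, so reads of overlapping or antisense genes may be shared between them.

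Each deposited file per library holds raw read counts for 16868 FlyBase genes, without normalization. The deposited tables per comparison hold the authors' log2 fold changes and, per the file headers, their p-value and adjusted p-value for each gene, of which 10 tables compare an added Y with its control. These were used only to set the authors' values beside those fitted here, and 5 deposited tables that combine comparisons were not used. Tables and files that write "cs" for a group were read as Yohio, which is the genotype the labels give for those libraries. Symbols were found for 16648 gene IDs, and 16649 had a place in the Ensembl BDGP6.54 annotation, release 115; positions are those of that annotation, and the authors' build is not given. There were 106 sets of genes, 221 genes in all, with identical counts in every library and at least 100 counts in total, so near-identical copies such as Suppressor of Stellate, Hsp70 and histone genes have uncertain individual counts.

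Total counts per library ranged from 6026258 upward, and each library's limit for a count of 0 was taken as 3 counts. Ratios against a group with 0 counts in both libraries were computed against the mean of both libraries' limits, which is 3 counts in each library over its TMM-scaled total, and ratios with 1 to 3 counts carry a 95% exact counting interval. Such intervals and limits cover counting error only. The labels call the replicates biological but do not say whether they came from separate flies or cultures, so p-values measure the spread between libraries.

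Counts were fitted with edgeR 4.0.16 (R 4.3.3) in 5 fits, 1 for each tissue and sex with its 6 libraries and 3 genotypes. Genes were kept with filterByExpr at a minimum count of 10, libraries were scaled with TMM, and quasi-likelihood tests were made for each added Y against its control and for the 2 added Y chromosomes against each other, with 3 residual degrees of freedom. In addition, 4 differences of differences were tested on 12 libraries each: female against male body and female body against ovary, for Yohio and for Ycongo. The p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called. With 2 against 2 libraries, an exact two-sided permutation test of a single value cannot go below 0.333, so none was made. The biological coefficient of variation was 0.41 in female bodies, 0.3 in ovaries, 0.24 in the CNS, 0.37 in male bodies and 0.28 in testes.

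The 36 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, where at least 3 genes of a list were tested, and adjusted over the lists of a contrast. Camera compares a list with all other genes. As a second method, fry tested whether the genes of a list move, on balance, one way, which does not compare them with other genes. The lists, contrasts, tests, alternatives and the rule for naming genes were chosen before the data were examined.

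By that rule the text could name the 12 protein-coding Y genes in every tissue, and for each contrast up to 6 higher and 6 lower called genes with the largest changes, a mean log2 CPM of at least 2 and no overlap between groups. It also allowed up to 5 genes per direction called with both added Y chromosomes, up to 4 called members of a called list, and up to 5 genes per direction of a difference of differences. Genes named although edgeR did not call them, other than the protein-coding Y genes, were chosen after their values were seen, mostly as members of a list with small p-values, and so were the called genes mt:ND2, mt:CoIII, CG8500, Mrm2 and nmo. Also chosen after the values were seen were the sums over the 34 Suppressor of Stellate repeats, over the Stellate repeats and over the Y genes other than FDY, which were each fitted as 1 gene beside all others.

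The following alternatives were planned: RLE in place of TMM scaling, no filter on low counts, DESeq2 1.42.0 in place of edgeR, a fit on the 4 libraries of a contrast alone, replicate number as a block, leaving out each library in turn, and for lists a correlation estimated from the data. Leaving out mitochondrially encoded genes from library sizes and tests was added after seeing the data. Where a group was left with 1 library, that library was assumed to vary like the other groups.

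The edgeR procedure was tested on simulated data with the depth and spread of each tissue, in which 100 genes changed 2-fold and 100 changed 4-fold. For Yohio against control it recovered 0% and 7% of them in female bodies, 5% and 84% in ovaries, 40% and 92% in the CNS, 1% and 16% in male bodies, and 12% and 84% in testes. In the same simulated sets it also called 1, 7, 13, 4 and 7 genes that had not been changed, in the same order of tissues, and for Ycongo, where nothing had been changed, 0, 0, 5, 0 and 1. The counts of called genes and their overlaps between both added Y chromosomes were compared with 20 simulated data sets per tissue without a change, in which genes were drawn independently of each other. Each gene was drawn with the dispersion estimated for it from the 6 libraries, so the error of that estimate counts as real spread there. The comparison of the counts of called genes was added after the calls were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.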

Results

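Poly(A) RNA of Drosophila melanogaster flies that carried an added Y chromosome was compared with that of control flies without it, in 30 libraries that form 15 groups of 2. Females without a Y (XX) were compared with females that carried a Y named Yohio or Ycongo (XXYohio, XXYcongo), and males with 1 Y (XY) with males that carried a further Yohio or Ycongo (XYYohio, XYYcongo). Whole bodies of both sexes, ovaries and testes came from adults, whose age was given as 2 days, and the central nervous system (CNS) came from third-instar female larvae. Total counts per library lay between 7742372 and 14013900 for female bodies, 8595497 and 15363636 for ovaries, 7621456 and 10108413 for the CNS, 6026258 and 12754207 for male bodies, and 7685847 and 14663482 for testes. The limit that a count of 0 allows, 3 counts, lay between 0.193 and 0.409 CPM per library, where CPM are counts scaled to a common library total with TMM factors. Values are CPM as mean ± SD over the 2 libraries of a group, and a fitted log2 fold change carries its standard error (SE).

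The first question was what Yohio changed in the female body. RNA of Y-linked repeats appeared in XXYohio females. The Suppressor of Stellate repeats, 34 near-identical Y copies whose RNA silences the X-linked Stellate genes, had no count in either XX body library and 56.4 ± 50.3 CPM (SD, n = 2) in XXYohio bodies, at least 233-fold higher than the mean limit of both XX libraries. FDY (FBgn0265047), a protein-coding Y gene that is a copy of the autosomal gene vig2, went from 0.331 ± 0.159 to 11.2 ± 1.78 CPM (n = 2), which is 33.8 times as much. The other 11 protein-coding Y genes, most of which serve the sperm tail, stayed at or under 0.648 CPM on average in every female group. Transcripts of the thorax and the eye stood lower: upheld (up, a troponin T of muscle) stood at 70.3 ± 13.1 CPM in XX and 22.6 ± 2.3 CPM in XXYohio (n = 2). The major rhodopsin ninaE stood at 580 ± 23.7 and 200 ± 58.7 CPM, and the light-gated channel gene trp at 71.4 ± 11.5 and 19.1 ± 3.56 CPM. Cell cycle transcripts stood higher, such as the spindle checkpoint kinase BubR1 with 128 ± 4.71 CPM in XX and 405 ± 54.2 CPM in XXYohio and the replication helicase subunit Mcm5 with 86.4 ± 8.06 and 213 ± 11.2 CPM.

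None of these single genes passed the test in the female body with Yohio. With edgeR, 0 of 10459 genes had an adjusted p below 0.05, 978 had an unadjusted p under 0.05, and DESeq2 called 9 higher and 5 lower. FDY had an adjusted p of 0.283 with edgeR and 1.42e-07 with DESeq2, and the summed Suppressor of Stellate repeats had an adjusted p of 0.202. Beyond FDY and repeats, the DESeq2 calls included the chorion gene Cp19, at 31.8 ± 8.1 CPM in XX and 201 ± 138 CPM in XXYohio (DESeq2 adjusted p = 0.00295). They also included CG31199, at 63.4 ± 4.72 and 13.0 ± 1.35 CPM (DESeq2 adjusted p = 0.00295). As sets compared with all other genes by camera, 27 muscle genes moved down (25 of 27 below 0, median log2 fold change -1.21, adjusted p = 3.49e-10 and adjusted p = 0.415 with an estimated correlation). The 26 photoreceptor genes had a median of -0.88 (adjusted p = 2.3e-07 and adjusted p = 0.415 with an estimated correlation). Of 41 cell cycle genes, 40 lay above 0 with a median of 0.72 (adjusted p = 3.49e-10 and adjusted p = 0.415 with an estimated correlation). Germline and ovary lists moved up in the same contrast: 40 of 45 female germline genes lay above 0 (median 0.45, adjusted p = 7.14e-07 and adjusted p = 0.483 with an estimated correlation). Whole bodies include the ovaries, and whether the shares of tissues differed between groups was not tested, so shifts of such lists need not be changes within cells. The 31 eggshell genes, which follicle cells express, had a median of 0.65 (adjusted p = 1.95e-05 and adjusted p = 0.502 with an estimated correlation), and the 35 piRNA pathway genes had a median of 0.38 (adjusted p = 0.000198 and adjusted p = 0.502 with an estimated correlation). Adjusted over the list alone, 7 muscle genes and 5 photoreceptor genes were lower and 1 eggshell gene was higher, against 0 called over all genes. The preset-correlation p became 0.119 for eggshell genes without XXYohio replicate 2 and 0.181 for piRNA pathway genes without XX replicate 2, while the other 4 lists were called whichever library was left out.

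The same question for Ycongo in the female body gave the same Y-linked transcripts. The Suppressor of Stellate repeats reached 68.9 ± 38.1 CPM (n = 2), at least 284-fold above the mean XX limit, and FDY reached 8.43 ± 1.56 CPM, 25.5 times its XX level. Antimicrobial and related immune peptides stood lower, with Daisho1 (Dso1) at 42.1 ± 21.8 CPM in XX and 9.83 ± 2.67 CPM in XXYcongo and the Baramicin gene BaraA1 at 32.3 ± 19.7 and 7.7 ± 1.84 CPM. Gut enzymes stood lower too, such as the protease Jon74E at 76.1 ± 40.6 and 16.1 ± 6.53 CPM and the lysozyme LysP at 137 ± 29.9 and 58.0 ± 1.69 CPM. Rhodopsin ninaE stood at 225 ± 13.7 CPM, below its XX level as with Yohio.

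With edgeR, 0 of 10459 genes were called for Ycongo in the female body, 447 had an unadjusted p under 0.05, and DESeq2 called 6 higher and 0 lower. FDY had an adjusted p of 0.507 with edgeR and 4.65e-06 with DESeq2. By camera, 32 antimicrobial genes moved down (30 of 32 below 0, median -1.88, adjusted p = 9.92e-11 and adjusted p = 0.385 with an estimated correlation). The 51 digestive enzyme genes did so as well (48 of 51 below 0, median -0.94, adjusted p = 2.61e-10 and adjusted p = 0.389 with an estimated correlation). The 45 female germline genes moved up (41 above 0, median 0.63, adjusted p = 6.53e-10 and adjusted p = 0.385 with an estimated correlation). Eggshell genes (median 0.55, adjusted p = 1.77e-06 and adjusted p = 0.389 with an estimated correlation) and cell cycle genes (median 0.44, adjusted p = 3.17e-07 and adjusted p = 0.385 with an estimated correlation) moved up as well. So did 30 mitochondrially encoded genes (30 of 30 above 0, median 1.84, adjusted p = 1.32e-08 and adjusted p = 0.542 with an estimated correlation). Adjusted over the list alone, 0 antimicrobial genes were lower. Leaving out any 1 library kept each of these 6 list calls with the preset correlation. The share of all counts that came from the mitochondrial genome was 25.17% and 9.26% in the XX bodies, 33.25% and 5.21% in XXYohio, and 25.44% and 33.49% in XXYcongo, so it varied as much between libraries of 1 group as between groups. The direct comparison of XXYcongo with XXYohio bodies gave 0 genes by edgeR, 137 at an unadjusted p under 0.05, and 0 by DESeq2.

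**Figure D1:**
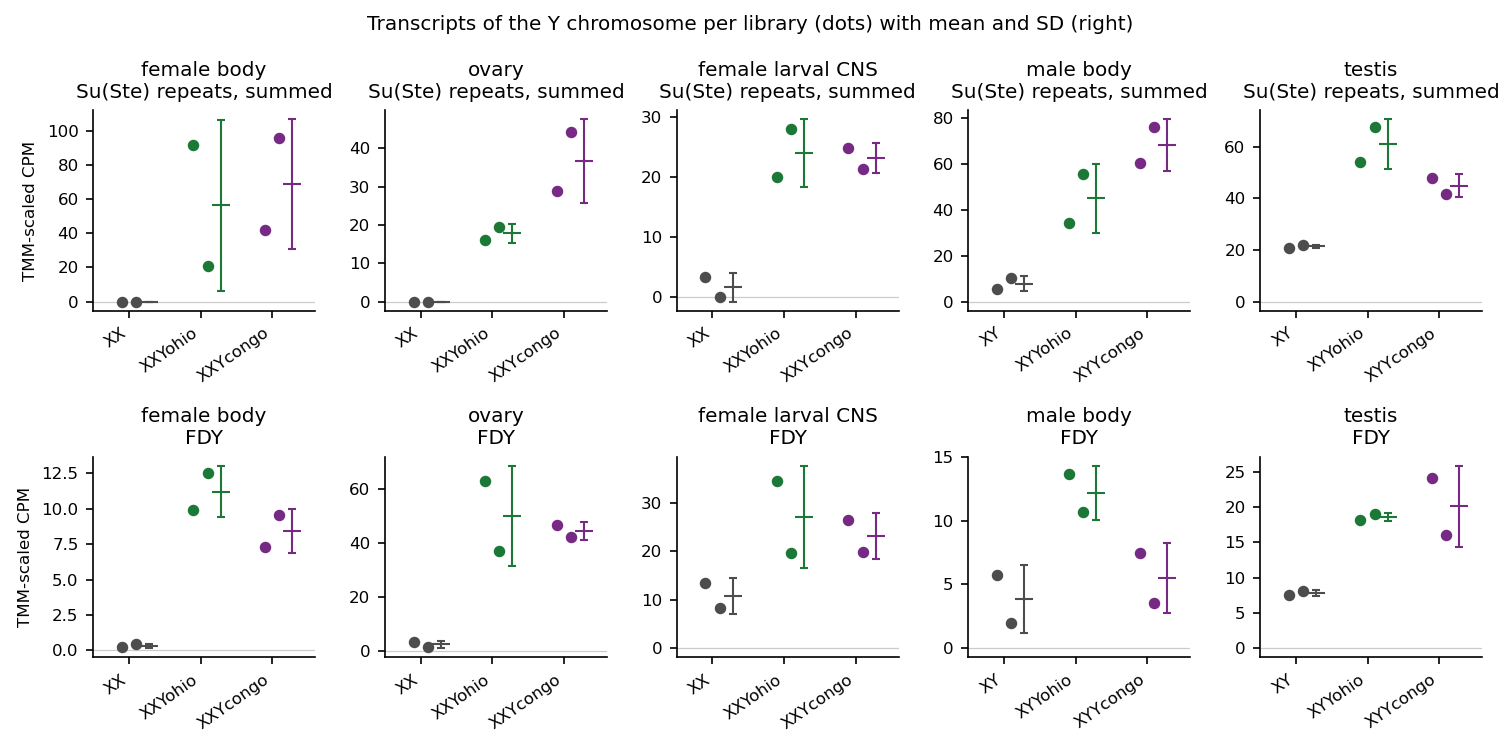
CPM of the summed Suppressor of Stellate repeats (top) and of FDY (bottom) in each library, by tissue and genotype, with the mean and SD of each group at the right of its points. In ovaries the repeats had 0 counts in both XX libraries and means of 17.8 and 36.6 CPM with Yohio and Ycongo.

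In the ovary the question was the same, and with Yohio the single gene called was Y-linked. FDY rose from 2.48 ± 1.4 CPM in XX to 50.1 ± 18.6 CPM in XXYohio (n = 2), 20.2 times as much (log2 fold change 4.34 ± 0.47 SE, adjusted p = 0.031 by edgeR). EdgeR called no other gene among 8829 tested. The adjusted p of FDY was 0.262 without XX replicate 1, 0.475 without XX replicate 2, 0.587 without XXYohio replicate 1 and 0.154 without XXYohio replicate 2, and its DESeq2 adjusted p was 2.44e-16. The summed Suppressor of Stellate repeats had 0 counts in XX ovaries and 17.8 ± 2.42 CPM in XXYohio ovaries, at least 58.9-fold above the mean XX limit (adjusted p = 0.00443 for the sum). Heat shock genes stood lower: Hsp70Bb (FBgn0013278), 1 of several near-identical Hsp70 copies, had 28.3 ± 3.4 CPM in XX and 4.23 ± 1.02 CPM in XXYohio (adjusted p = 0.214). The stress-induced nuclear RNA lncRNA:Hsromega stood at 271 ± 177 CPM in XX and 54.4 ± 13.3 CPM in XXYohio (n = 2). By camera, 22 heat shock genes moved down (19 of 22 below 0, median -1.2, adjusted p = 7.33e-10 and adjusted p = 0.339 with an estimated correlation), with 11 lower when adjusted over the list alone against 0 over all genes. The 28 mitochondrially encoded genes, tRNAs among them, were all below 0 with a median of -1.4 (adjusted p = 8.54e-12 and adjusted p = 0.449 with an estimated correlation). In all, 620 genes had an unadjusted p under 0.05, and DESeq2 called 7 higher and 16 lower. The number of genes called by edgeR was 0 without any XX or XXYohio library, 27 without XXYcongo replicate 1 and 46 without XXYcongo replicate 2. In 7 of 20 data sets simulated without a change, edgeR called at least as many genes as the 1 called here.

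Lists of other tissues moved down in XXYohio ovaries as well by camera. The 23 muscle genes (20 below 0) had a median of -0.56 (adjusted p = 0.000101 and adjusted p = 0.449 with an estimated correlation), and the p with the preset correlation became 0.0768 without XXYohio replicate 2. The 14 neuronal genes had a median of -0.78 (adjusted p = 0.000651 and adjusted p = 0.501 with an estimated correlation), with 0.0759 without XX replicate 1. The 8 photoreceptor genes had a median of -0.42 (adjusted p = 0.00751 and adjusted p = 0.449 with an estimated correlation), with 0.131 without XX replicate 1 and 0.0839 without XXYohio replicate 1. The 12 glial genes had a median of -0.33 (adjusted p = 0.0395 and adjusted p = 0.449 with an estimated correlation) and were called whichever library was left out. The 9 hemocyte genes had a median of -0.11 (adjusted p = 0.0429 and adjusted p = 0.449 with an estimated correlation), with 0.0759, 0.385, 0.631, 0.183 and 0.197 without XX replicates 1 and 2, XXYohio replicate 2 and XXYcongo replicates 1 and 2. Adjusted over the list alone, 2 hemocyte genes and 0 genes of the other 4 lists were lower, against 0 over all genes. With Ycongo, photoreceptor genes moved down (median -0.58, adjusted p = 0.0289 and adjusted p = 0.649 with an estimated correlation), with 0.394 without XX replicate 1 and 0.152 without XXYcongo replicate 1, and 1 was lower adjusted over the list alone against 0 over all genes. Muscle genes (median 0.25, adjusted p = 0.029 and adjusted p = 0.777 with an estimated correlation) and hemocyte genes (median 0.73, adjusted p = 0.00191 and adjusted p = 0.777 with an estimated correlation) were higher with Ycongo than with Yohio. The muscle list had 0.224 and 0.21, and the hemocyte list 0.186 and 0.255, without XXYohio replicate 2 and XXYcongo replicate 1, and 5 and 2 of their genes were higher adjusted over the list alone against 0 over all genes.

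With Ycongo, 4 genes rose and 21 fell in the ovary by edgeR, among 962 with an unadjusted p under 0.05, while DESeq2 called 44 higher and 141 lower. The edgeR total was 2 without XX replicate 1, 11 without XX replicate 2, 6 without either XXYohio replicate, 496 without XXYcongo replicate 1 and 260 without XXYcongo replicate 2. Of 20 data sets simulated without a change, 0 reached 25 calls, and the highest had 5. Genes were drawn independently there, whereas mitochondrially encoded genes, which many of the calls were, can move together. The comparison therefore cannot say how often variation shared by the genes of a library gives 25 calls. All 4 genes that rose were Y-linked. FDY rose to 44.6 ± 3.27 CPM (n = 2), 18.0 times its XX level (log2 fold change 4.18 ± 0.47 SE, adjusted p = 0.00806), with an adjusted p of 0.0781 without XX replicate 1 and 0.0913 without XX replicate 2. The other 3 were Suppressor of Stellate repeats that had 0 counts in XX ovaries: Su(Ste):CR42425 was at least 10.7-fold higher, Su(Ste):CR42430 at least 16.5-fold and Su(Ste):CR42433 at least 20.2-fold, each against the mean XX limit (adjusted p = 0.0445, 0.049 and 0.0445). Their adjusted p was 0.456, 0.495 and 0.456 without XX replicate 1, 0.247, 0.268 and 0.256 without XX replicate 2, 0.203, 0.165 and 0.203 without XXYohio replicate 1, and 0.234, 0.165 and 0.209 without XXYohio replicate 2. Without mitochondrially encoded genes in library sizes and tests, an alternative added after seeing the data, FDY kept its call (adjusted p = 0.0197) and the 3 repeats did not (adjusted p = 0.0747, 0.0797 and 0.0747). Together the repeats reached 36.6 ± 10.9 CPM, at least 121-fold above the mean XX limit (adjusted p = 0.00158 for the sum). Reads of such copies are hard to assign to 1 of them, so the sum is firmer than any single repeat.

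Most of the strongest losses in XXYcongo ovaries were transcripts of the mitochondrial genome. The complex I subunit mt:ND3 fell from 1010 ± 590 CPM in XX to 11.4 ± 6.2 CPM in XXYcongo (n = 2, log2 fold change -6.45 ± 0.62 SE, adjusted p = 0.00499), and stood at 452 ± 136 CPM in XXYohio. The ATP synthase subunit mt:ATPase8 fell from 447 ± 122 to 9.3 ± 7.64 CPM (log2 fold change -5.55 ± 0.59 SE, adjusted p = 0.00647, and 0.0924 without XX replicate 1). Another complex I subunit, mt:ND2, fell from 2820 ± 1900 to 145 ± 6.96 CPM (adjusted p = 0.00981), with an adjusted p of 0.0727 without XX replicate 1, 0.0696 without XXYohio replicate 1 and 0.0691 without XXYohio replicate 2. The cytochrome oxidase subunit mt:CoIII fell from 11000 ± 1130 to 1890 ± 552 CPM (adjusted p = 0.0445), with 0.456 without XX replicate 1, 0.216 without XX replicate 2 and 0.165 without either XXYohio replicate. The complex I subunit mt:ND6 fell from 330 ± 235 to 8.66 ± 6.9 CPM (adjusted p = 0.0156, and 0.155, 0.117 and 0.113 without XX replicate 1 and XXYohio replicates 1 and 2). The most abundant one, mt:CoI, stood at 42800 ± 19400 in XX and 13000 ± 6070 CPM in XXYcongo and did not pass (adjusted p = 0.274). The losses were thus unequal: the authors' log2 fold changes were -4.56 for mt:ND3, but -1.32 for mt:CoI, -1.5 for mt:ND4 and -1.63 for mt:Cyt-b. The fall of mt:ND3 is therefore not that of mitochondrial mRNA as a whole. Whether the size of a loss depended on the length of the transcript was not tested. As a list, 28 of 28 mitochondrially encoded genes lay below 0 (median -3.91, adjusted p = 1.75e-33 and adjusted p = 0.386 with an estimated correlation), and 26 were lower adjusted over the list alone against 10 called over all genes. The mitochondrial share of counts was 12.79% and 8.18% in XX ovaries, 4.82% and 6.61% in XXYohio, and 1.81% and 4.17% in XXYcongo. Since RNA was selected by its poly(A) tail, counts of mitochondrial tRNAs, of which 5 were called lower, reflect only what that selection carried along. The list holds such tRNAs beside mRNAs, so its median is not the size of the loss of mitochondrial mRNA. The lowest ratio among them was that of mt:tRNA:Ala-TGC, 0.00337 (95% counting interval 0.000693 to 0.00988, adjusted p = 0.00499). The next was mt:tRNA:Asp-GTC with 0.00945 (0.00194 to 0.0279, adjusted p = 0.00647, and 0.0947 without XX replicate 1). For mt:tRNA:Met-CAT it was 0.0133 (0.00271 to 0.0394, adjusted p = 0.0408, and 0.456, 0.165 and 0.165 without XX replicate 1 and XXYohio replicates 1 and 2).

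**Figure D2:**
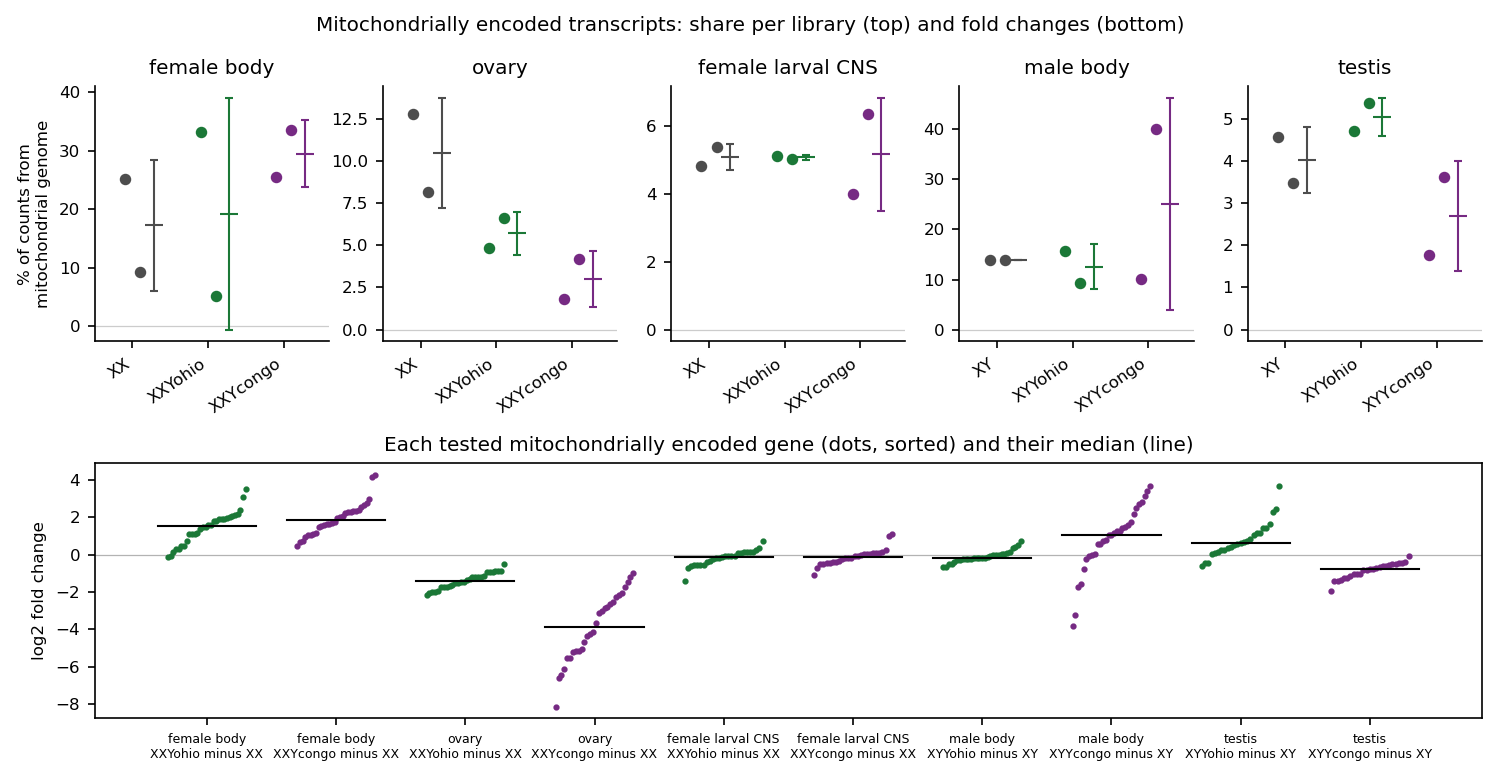
Share of counts from the mitochondrial genome in percent for each library (top) and log2 fold change of each tested mitochondrially encoded gene with its median line for each contrast of an added Y with control (bottom). In XXYcongo ovaries 28 of 28 genes, tRNAs among them, lay below 0 with a median of -3.91, whereas in XXYcongo female bodies 30 of 30 lay above 0.

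Nuclear genes also fell in XXYcongo ovaries. The mitochondrial rRNA methyltransferase gene Mrm2 (3R, 19861610 to 19862600 in the BDGP6.54 annotation) fell from 64.5 ± 6.14 to 11.5 ± 0.00979 CPM (n = 2, log2 fold change -2.49 ± 0.29 SE, adjusted p = 0.00934). CG8500 (3R, 9784653 to 9789323), a predicted small GTPase of the Ras family, fell from 70.2 ± 8.16 to 6.57 ± 3.11 CPM (log2 fold change -3.39 ± 0.39 SE, adjusted p = 0.00806). The kinase gene nemo (nmo, 3L, 7979046 to 8054147), which acts in planar polarity and follicle cells, fell from 474 ± 93.7 to 144 ± 6.07 CPM (log2 fold change -1.72 ± 0.29 SE, adjusted p = 0.049). Hsp70Bb fell from 28.3 ± 3.4 to 4.56 ± 1.07 CPM (log2 fold change -2.64 ± 0.4 SE, adjusted p = 0.0408). The anterior determinant bicoid (bcd) stood at 290 ± 27.1 CPM in XX and 99.6 ± 1.27 CPM in XXYcongo, with an adjusted p of 0.0515 in edgeR and 1.82e-05 in DESeq2. By camera the heat shock list moved down again (19 of 22 below 0, median -0.79, adjusted p = 2.52e-07 and adjusted p = 0.341 with an estimated correlation), with 9 lower adjusted over the list alone against 1 over all genes.

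Most nuclear calls were lost without mitochondrially encoded genes in library sizes and tests: of the 15 called genes outside the mitochondrial genome, 3 kept their call and 12 did not. Mrm2 and CG8500 kept theirs with FDY (adjusted p = 0.0197 each), whereas Hsp70Bb (adjusted p = 0.0736) and nmo (adjusted p = 0.0797) lost theirs. Their log2 fold changes moved little, to -2.5, -3.4, -2.65 and -1.72 for Mrm2, CG8500, Hsp70Bb and nmo. The Benjamini-Hochberg adjustment depends on how many genes have smaller p-values. Removing called genes therefore raises the adjusted p of those ranked below them by construction. The lost calls do not by themselves show that these nuclear changes depended on mitochondrial reads.

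These 4 nuclear calls were lost without some single ovary libraries, among them XXYohio libraries outside the contrast, and kept without either XXYcongo replicate. Over the 6 libraries left out, the log2 fold changes lay between -2.64 and -2.38 for Mrm2, -4.0 and -2.99 for CG8500, -2.88 and -2.4 for Hsp70Bb, and -1.96 and -1.48 for nmo, so the directions held. Mrm2 had an adjusted p of 0.155 without XX replicate 1, 0.0542 without XX replicate 2, 0.0696 without XXYohio replicate 1 and 0.0691 without XXYohio replicate 2. CG8500 had 0.147 without XX replicate 1, 0.0635 without XXYohio replicate 1 and 0.0627 without XXYohio replicate 2. Hsp70Bb had 0.456 without XX replicate 1, 0.16 without XX replicate 2 and 0.165 without either XXYohio replicate, while the adjusted p of nmo was 0.495, 0.16, 0.229 and 0.234 without XX replicates 1 and 2 and XXYohio replicates 1 and 2. By contrast, mt:ND3 was called whichever library was left out (highest adjusted p = 0.0331). Between the ovaries of the 2 added Y chromosomes, edgeR called mt:ND3 alone, lower with Ycongo, among 720 genes with an unadjusted p under 0.05, and DESeq2 called 15 higher and 28 lower. That call had an adjusted p of 0.0569 without XX replicate 1, 0.202 without XXYohio replicate 1 and 0.274 without XXYohio replicate 2, and the number of genes called was 0 without XX replicate 1 or either XXYohio replicate, 2 without XX replicate 2, 197 without XXYcongo replicate 1 and 198 without XXYcongo replicate 2. In 10 of 20 data sets simulated without a change, edgeR called at least 1 gene in that contrast.

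With fry, which asks whether the genes of a list move on balance one way, 3 ovary lists passed. The 8 tested Stellate and Suppressor of Stellate repeats were higher with Yohio (fry adjusted p = 0.0418) and Ycongo (fry adjusted p = 0.0221), with medians of 2.37 and 3.23 on the log2 scale when repeats at 0 counts in XX were set to their bound. By camera they had an adjusted p = 2.6e-16 and adjusted p = 0.339 with an estimated correlation for Yohio, and an adjusted p = 5.16e-17 and adjusted p = 0.341 with an estimated correlation for Ycongo. Adjusted over the list alone 8 repeats were higher with each, against 0 and 3 over all genes. All 8 had 0 counts in both XX libraries, which carry no Y, and passed the filter on low counts only through XXY libraries. The direction of this list was thus given by the genotype, so its call checks the presence of the Y and not a response to it. The 14 fat body genes, which encode mostly secreted and storage proteins, were lower with Ycongo (median -0.85, fry adjusted p = 0.000277, camera adjusted p = 0.00118 and adjusted p = 0.341 with an estimated correlation). Adjusted over the list alone, 3 were lower and 1 higher, against 0 over all genes. By fry they were also lower with Yohio (median -0.3, fry adjusted p = 0.0258) and with Ycongo against Yohio (median -0.46, fry adjusted p = 0.0159). Camera called neither (adjusted p = 0.0609 and adjusted p = 0.449 with an estimated correlation for Yohio, adjusted p = 0.0971 and adjusted p = 0.777 with an estimated correlation for Ycongo against Yohio), and 1 and 0 genes were lower adjusted over the list alone. The larval serum protein gene Lsp2 among them stood at 12.1 ± 4.83 CPM in XX and 0.876 ± 0.403 CPM in XXYcongo (n = 2). The third was a list of 4 cuticle genes, higher with Yohio by fry (fry adjusted p = 0.0459) but not by camera (adjusted p = 0.456 and adjusted p = 0.641 with an estimated correlation), with 2 genes above 0 and 2 below. Outside the ovary, fry called the Stellate and Suppressor of Stellate repeats in the CNS with Yohio (fry adjusted p = 0.0382, camera adjusted p = 1.16e-14 and adjusted p = 0.232 with an estimated correlation) and no other list. There 7 repeats were higher adjusted over the list alone, against 0 over all genes. XX larvae carry no Y either, so that direction too was given by the genotype.

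In the larval CNS the question was again what each added Y changed, and the calls were few enough that simulated data without a change often gave as many. ImpE2 (FBgn0001254; 3L, 3510974 to 3512681), an ecdysone-inducible gene of disc eversion, fell from 162 ± 27.5 CPM in XX to 44.5 ± 4.34 CPM in XXYohio (n = 2, log2 fold change -1.86 ± 0.18 SE, adjusted p = 0.0281) and to 10.4 ± 1.04 CPM in XXYcongo (log2 fold change -3.95 ± 0.2 SE, adjusted p = 0.000422). Its levels with the 2 added Y chromosomes also differed from each other (log2 fold change -2.09 ± 0.19 SE for XXYcongo minus XXYohio, adjusted p = 0.0213). The larval cuticle protein gene Lcp3 (2R, 8435310 to 8436095) rose from 3.18 ± 0.576 to 68.7 ± 6.84 CPM with Yohio, 21.6 times as much (adjusted p = 0.00221), and stood at 3.7 ± 0.961 CPM with Ycongo (adjusted p = 0.918). Its neighbour Lcp4 (2R, 8437647 to 8438495) rose from 10.6 ± 1.4 to 96.5 ± 39.9 CPM with Yohio, 9.07 times as much (adjusted p = 0.0385), and stood at 7.63 ± 2.44 CPM with Ycongo. Both differed between the added Y chromosomes, Lcp3 by a log2 fold change of -4.21 ± 0.27 SE (adjusted p = 0.00301) and Lcp4 by -3.65 ± 0.36 SE (adjusted p = 0.0233). CG7906, of unknown function, fell with Yohio from 94.7 ± 79.0 CPM to a ratio of 0.000581 (95% counting interval 1.47e-05 to 0.00324, adjusted p = 0.0288), and its ratio with Ycongo was 0.000689 (interval 1.74e-05 to 0.00384, adjusted p = 0.0521).

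Genes that DESeq2 called in the CNS and edgeR did not included the ecdysone-induced repressor gene Blimp-1, which had 43.4 ± 9.05 CPM in XX, 11.2 ± 1.02 CPM in XXYohio and 9.79 ± 4.38 CPM in XXYcongo (n = 2 each), with DESeq2 adjusted p values of 0.000118 and 1.11e-05. The nuclear receptor gene Hr3 had 46.8 ± 5.15, 19.2 ± 2.9 and 17.7 ± 5.92 CPM (DESeq2 adjusted p values of 0.0102 and 0.00339). The germ cell differentiation gene bam stood higher, with 1.32 ± 0.642 CPM in XX, 11.1 ± 4.09 CPM in XXYohio and 7.23 ± 1.13 CPM in XXYcongo (DESeq2 adjusted p values of 0.000199 and 0.0116). By camera, 14 cuticle genes moved up with Yohio (median 2.1, adjusted p = 7.33e-06 and adjusted p = 0.615 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone against 2 higher over all genes. With Ycongo, 105 histone genes moved up (87 above 0, median 0.57, adjusted p = 1.75e-12 and adjusted p = 0.787 with an estimated correlation) and 52 neuronal genes moved down (42 below 0, median -0.32, adjusted p = 0.000192 and adjusted p = 0.813 with an estimated correlation). Histone genes are near-identical copies whose mature transcripts mostly lack a poly(A) tail, so their counts are uncertain.

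Lists of other tissues and of metabolism moved in the CNS too. With Yohio, 43 detoxification genes moved up (34 above 0, median 0.51, adjusted p = 0.00354 and adjusted p = 0.888 with an estimated correlation), with a preset-correlation p of 0.54 without XXYohio replicate 2. The 36 lipid and sugar metabolism genes moved up (29 above 0, median 0.26, adjusted p = 0.000576 and adjusted p = 0.615 with an estimated correlation) whichever library was left out. With Ycongo, 14 hemocyte genes moved down (median -0.51, adjusted p = 0.0192 and adjusted p = 0.787 with an estimated correlation), with 0.183 without XX replicate 2 and 0.244 without XXYcongo replicate 1. Between the added Y chromosomes, cuticle genes were lower with Ycongo (13 of 14 below 0, median -2.91, adjusted p = 4.78e-15 and adjusted p = 0.33 with an estimated correlation) whichever library was left out, with 10 lower adjusted over the list alone against 2 over all genes. Lower in that contrast were also muscle genes (median -0.31, adjusted p = 0.000154 and adjusted p = 0.565 with an estimated correlation), hemocyte genes (median -0.3, adjusted p = 0.0023 and adjusted p = 0.565 with an estimated correlation) and genes of the hormone-making ring gland (median -0.95, adjusted p = 0.0139 and adjusted p = 0.565 with an estimated correlation). So were detoxification genes (median -0.37, adjusted p = 0.000295 and adjusted p = 0.668 with an estimated correlation), immune recognition genes (median -0.26, adjusted p = 0.00484 and adjusted p = 0.601 with an estimated correlation) and lipid and sugar metabolism genes (median -0.25, adjusted p = 0.0013 and adjusted p = 0.565 with an estimated correlation). Without XXYohio replicate 2 and XXYcongo replicate 1 the preset-correlation p became 0.0577 and 0.103 for muscle, 0.133 and 0.389 for detoxification and 0.0923 and 0.168 for lipid and sugar metabolism genes. Without XXYohio replicate 1 and XXYcongo replicate 1 it became 0.0961 and 0.139 for hemocyte, 0.215 and 0.814 for immune recognition and 0.268 and 0.168 for ring gland genes, which had 0.0563 without XXYcongo replicate 2. Adjusted over the list alone, 5 detoxification genes and 1 ring gland gene were lower in that contrast and 1 hemocyte gene with Ycongo, against 0 over all genes.

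**Figure D3:**
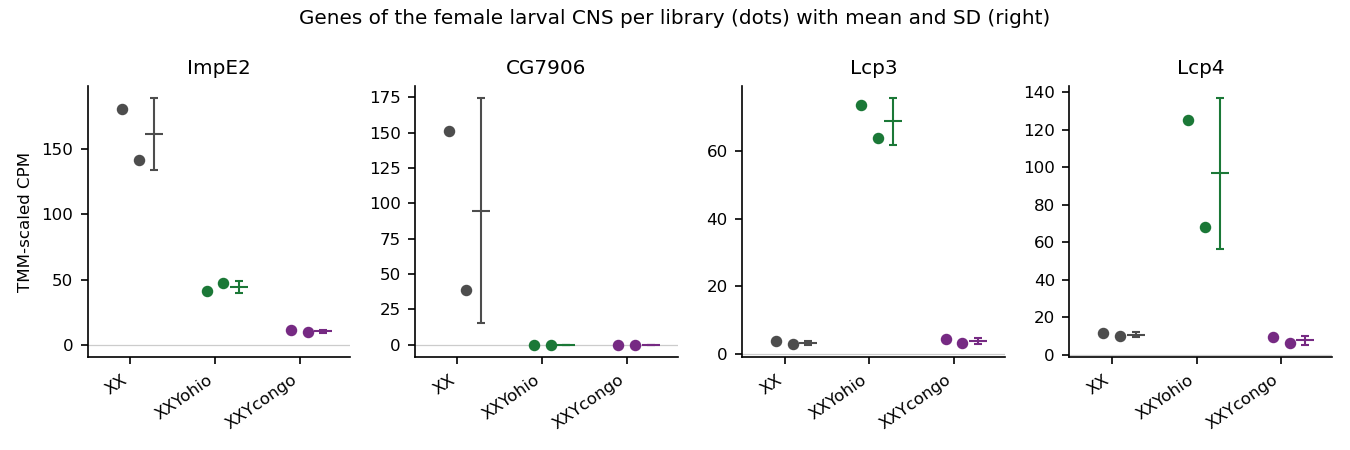
CPM of ImpE2, CG7906, Lcp3 and Lcp4 in each larval CNS library by genotype, with the mean and SD of each group. ImpE2 fell from a mean of 162 CPM in XX to 44.5 and 10.4 CPM with Yohio and Ycongo, whereas Lcp3 and Lcp4 rose with Yohio.

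In the CNS, edgeR called 2 genes higher and 2 lower with Yohio (584 at an unadjusted p under 0.05), 1 lower with Ycongo (513) and 3 lower with Ycongo than with Yohio (386), among 9936 tested. DESeq2 called 21 higher and 23 lower, 4 higher and 37 lower, and 0 higher and 54 lower. In 20 data sets simulated without a change, edgeR called at least as many genes as here in 9 for Yohio, in 11 for Ycongo and in 8 between the added Y chromosomes, with up to 9, 7 and 6 calls. The number of CNS calls therefore did not exceed that in the simulated data. There, 17, 11 and 17 of 20 sets held a call, more often than a threshold of 0.05 gives where its p-values hold. Dispersions estimated from 6 libraries were taken as true in the simulation, so their error counts as real spread. The sizes of p-values were not compared, so the comparison does not weigh single genes. Leaving out libraries changed the edgeR totals: for Yohio to 0 without XX replicate 1, 2 without XX replicate 2, 110 without XXYohio replicate 1 and 1 without either XXYcongo replicate. For Ycongo the total was 3 without XX replicate 2, 25 and 14 without XXYohio replicates 1 and 2, and 0 without either XXYcongo replicate. Between the added Y chromosomes it was 1 without either XX replicate, 185 without XXYohio replicate 1 and 0 without either XXYcongo replicate. For Yohio, ImpE2 had an adjusted p of 0.563 without XX replicate 1, 0.107 without XX replicate 2, 0.147 without XXYcongo replicate 1 and 0.126 without XXYcongo replicate 2. For Ycongo it had 0.0532 without XXYcongo replicate 1 and 0.0633 without XXYcongo replicate 2. Lcp3 with Yohio had 0.112 without XX replicate 1 and 0.0552 without XX replicate 2. Lcp4 had 0.976, 0.495, 0.147 and 0.126 without XX replicates 1 and 2 and XXYcongo replicates 1 and 2. CG7906 had 0.118 without XX replicate 1, 0.0757 without XXYohio replicate 2, 0.147 without XXYcongo replicate 1 and 0.126 without XXYcongo replicate 2. Between the added Y chromosomes, ImpE2 had 0.142, 0.132, 0.213 and 0.652, and Lcp4 0.199, 0.189, 0.213 and 0.7, without XX replicates 1 and 2 and XXYcongo replicates 1 and 2, whereas Lcp3 had 0.089 without XXYcongo replicate 1 and 0.13 without XXYcongo replicate 2. Over the 6 libraries left out, log2 fold changes with Yohio lay between -2.02 and -1.68 for ImpE2, 4.26 and 4.62 for Lcp3, and 2.69 and 3.55 for Lcp4. FDY in the CNS stood at 10.8 ± 3.73 CPM in XX, 27.1 ± 10.6 CPM in XXYohio and 23.3 ± 4.73 CPM in XXYcongo and did not pass (adjusted p = 0.727 and 0.855).

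In the male body the question was what a further Y adds to one already present. The Y of XY males is not named as Yohio or Ycongo, so the number and the kind of Y cannot be told apart. Female bodies with Yohio or Ycongo as the only Y had 56.4 and 68.9 CPM of the Suppressor of Stellate repeats, in a separate fit. The Suppressor of Stellate repeats had 7.73 ± 3.35 CPM in XY males, 44.9 ± 15.1 CPM in XYYohio and 68.1 ± 11.2 CPM in XYYcongo (n = 2 each), 5.8 and 8.8 times as much, with adjusted p values of 1 and 0.612 for the sum. The X-linked Stellate repeats, which they silence, stayed at 1.3 ± 0.324, 1.34 ± 0.868 and 1.68 ± 1.66 CPM. Protein-coding Y genes other than FDY summed to 162 ± 21.4 CPM in XY, 169 ± 42.8 CPM in XYYohio and 296 ± 133 CPM in XYYcongo. FDY stood at 3.85 ± 2.71, 12.2 ± 2.07 and 5.51 ± 2.75 CPM. The ETS-domain transcription factor gene Ets96B (FBgn0039225) stood at 17.9 ± 4.51 CPM in XY, 15.7 ± 1.91 CPM in XYYohio and 104 ± 11.7 CPM in XYYcongo, 5.81 times the XY level (adjusted p = 0.656 with edgeR and 0.000131 with DESeq2).

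EdgeR called 0 of 12889 genes in each of the 3 male body contrasts, with 60 at an unadjusted p under 0.05 for Yohio, 953 for Ycongo and 856 between them. DESeq2 called 0 for Yohio, 12 higher for Ycongo, and 14 higher and 2 lower between them. Between them it gave no adjusted p to 7497 of the 12889 genes, so its adjustment ran over fewer genes than that of edgeR. Without XYYcongo replicate 1, edgeR called 1 gene with Ycongo against XY and 1 against XYYohio. By camera the 10 tested Stellate and Suppressor of Stellate repeats moved up with both (median 2.5, adjusted p = 1.78e-23 and adjusted p = 0.183 with an estimated correlation for Yohio; median 3.11, adjusted p = 1.22e-11 and adjusted p = 0.493 with an estimated correlation for Ycongo). With genes at 0 counts set to their bound the medians were 2.19 and 2.73, and adjusted over the list alone 7 and 9 repeats were higher, against 0 over all genes. The mitochondrial share of counts was 13.98% and 13.95% in XY bodies, 15.71% and 9.37% in XYYohio, and 10.14% and 40.11% in XYYcongo.

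In the testis, where most protein-coding Y genes act, many of them stood higher with a further Y, and none passed in edgeR or DESeq2. The aldehyde reductase gene ARY stood at 91.0 ± 7.74 CPM in XY, 183 ± 23.3 CPM in XYYohio and 153 ± 14.1 CPM in XYYcongo (n = 2 each), 2.01 and 1.68 times as much. The sperm dynein heavy chain gene kl-5 had 201 ± 35.1, 353 ± 13.1 and 309 ± 119 CPM, and its relative kl-3 had 222 ± 62.9, 291 ± 0.785 and 243 ± 68.4 CPM. PRY, which serves sperm function, had 15.6 ± 6.59, 56.0 ± 7.61 and 34.1 ± 23.4 CPM, while Ppr-Y had 35.8 ± 3.28, 44.6 ± 1.35 and 35.2 ± 5.08 CPM. FDY had 7.83 ± 0.393, 18.6 ± 0.538 and 20.1 ± 5.74 CPM. The 11 genes other than FDY summed to 887 ± 146, 1410 ± 83 and 1170 ± 328 CPM, 1.58 and 1.32 times the XY level (adjusted p = 0.975 and 1). The Suppressor of Stellate repeats went from 21.4 ± 0.591 to 60.9 ± 9.7 and 44.9 ± 4.38 CPM, 2.85 and 2.1 times as much (adjusted p = 0.975 and 1). Whether their ratio differed from that of the protein-coding genes was not tested. Stellate itself stayed at 8.59 ± 3.51, 8.53 ± 1.63 and 7.88 ± 1.89 CPM. As in male bodies, the number and the kind of Y cannot be told apart in these ratios.

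No single testis gene passed in edgeR: 0 of 12743 genes were called in each contrast, with 370 at an unadjusted p under 0.05 for Yohio, 291 for Ycongo and 474 between them. DESeq2 called 3 higher and 1 lower for Yohio, 4 higher and 2 lower for Ycongo, and 1 higher and 7 lower between them. Without XYYcongo replicate 1, edgeR called 4 genes with Ycongo against XY and 4 against XYYohio. The DESeq2 calls included lncRNA:CR44189, with 0 counts in XY testes and 5.67 ± 1.29 and 7.2 ± 1.03 CPM (n = 2), at least 17.2-fold and at least 21.8-fold higher than the mean limit of both XY libraries. They also included the oenocyte cytochrome P450 gene Cyp4g1, with 7.98 ± 1.23 CPM in XY, 6.2 ± 0.597 CPM in XYYohio and 95.7 ± 57.9 CPM in XYYcongo. By camera, 12 of 12 protein-coding Y genes lay above 0 with Yohio (median 0.67, adjusted p = 2.86e-08 and adjusted p = 0.796 with an estimated correlation), with 3 higher adjusted over the list alone against 0 over all genes. With Ycongo 10 of 12 lay above 0 (median 0.44, adjusted p = 8.18e-05 and adjusted p = 0.806 with an estimated correlation), and the preset-correlation p became 0.218 without XYYcongo replicate 2. The 25 tested mitochondrially encoded genes were lower with Ycongo than with Yohio (median -1.35, adjusted p = 1.13e-19 and adjusted p = 0.764 with an estimated correlation), with 10 lower adjusted over the list alone against 0 over all genes.

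Whether an added Y acted differently by sex or tissue was tested directly. EdgeR called 0 genes for the difference between female and male bodies, with 668 at an unadjusted p under 0.05 for Yohio and 638 for Ycongo, and DESeq2 called 0 in both. Between female body and ovary, edgeR called 0 genes, with 897 and 1004 at an unadjusted p under 0.05, and DESeq2 called 0 higher and 1 lower for Yohio and 20 higher and 27 lower for Ycongo. For that Ycongo difference DESeq2 gave no adjusted p to 6280 of 10798 genes, so its adjustment ran over fewer genes than that of edgeR. The overlap of the 2 added Y chromosomes was 1 gene in the ovary (FDY, higher) and 1 in the CNS (ImpE2, lower). In the ovary it was 0 without any XX or XXYohio library and 17 and 25 without XXYcongo replicates 1 and 2, and in the CNS 0 without XX replicate 1 or either XXYcongo replicate, 2 without XX replicate 2 and 4 without XXYohio replicate 1. Both contrasts share 2 control libraries, so part of any overlap may come from them: data simulated without a change gave a mean of 0.1 and at most 1 shared gene in the ovary, and a mean of 0.6 and at most 4 in the CNS.

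**Figure D4:**
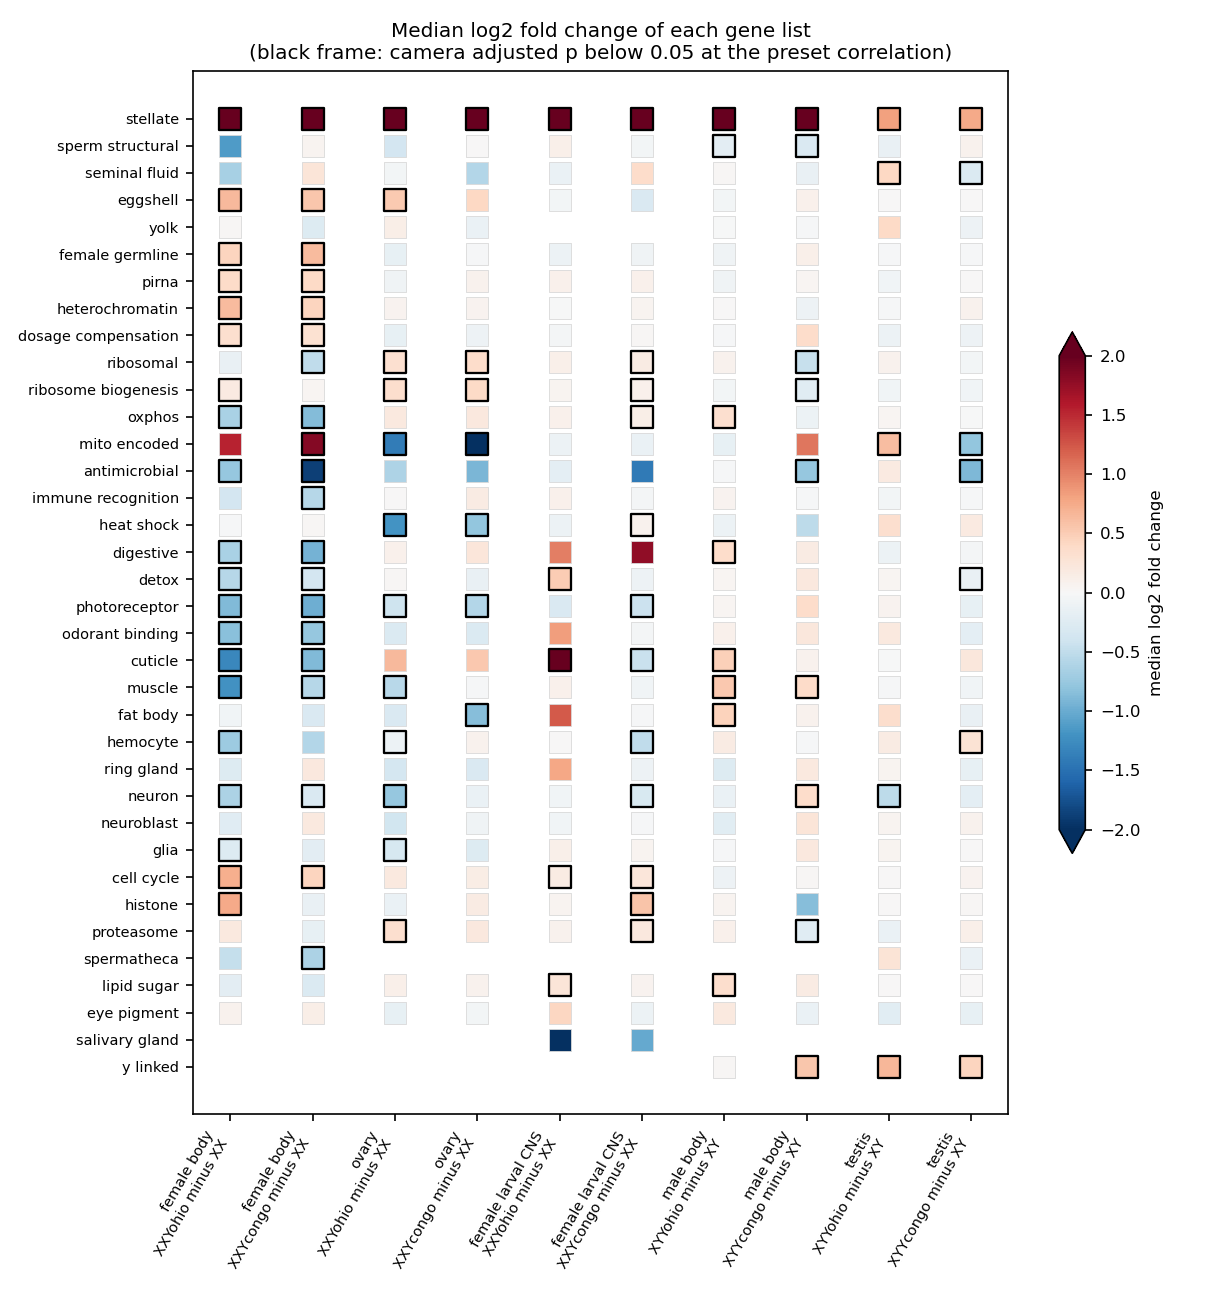
Median log2 fold change (colour, limited to the range from -2 to 2) of each gene list in the 10 contrasts of an added Y with control, with a black frame where the adjusted camera p was below 0.05 with the preset correlation. No list passed in any contrast when the correlation was estimated from the data, a test that rests on 3 residual degrees of freedom and can miss a list that moved.

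The authors' deposited tables, which hold a DESeq2 result per comparison, listed more genes than edgeR did here in every comparison but that of male bodies with Yohio, where both listed 0. In the authors' deposited table for the ovary with Ycongo, 15 genes were higher and 83 lower at an adjusted p below 0.05, and all 25 genes called here were among them. The authors' deposited table for the CNS with Ycongo held 13 higher and 131 lower genes, and the one for Yohio 43 higher and 46 lower, with all 4 genes called here among the latter. For ImpE2 in the CNS the authors' deposited table gave log2 fold changes of -1.76 with Yohio and -3.64 with Ycongo. For FDY in the ovary the authors' deposited table gave 2.97 and 3.0, smaller than the values fitted here. The 2 programs estimate fold changes differently, so their sizes are not directly comparable. In female bodies the authors' deposited table held 3 genes for Yohio and 7 for Ycongo, in male bodies 0 and 1 (Ets96B, log2 fold change 1.89), and in testes 11 and 8. Among the 11 testis genes for Yohio, the authors' deposited table held 3 protein-coding Y genes: PRY (log2 fold change 1.37, adjusted p = 0.00791), ARY (0.89, adjusted p = 0.0257) and FDY (1.03, adjusted p = 0.0338). Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those fitted here had correlations between 0.76 and 0.96.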

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

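The tests of mitochondrial sequence variants, of muscle in ovary samples and of XXY material in XX libraries were chosen after the result was seen; those of epidermis, ecdysone timing and vig2 reads were chosen before it.

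Of 35 lists, 22 had an adjusted camera p below 0.05 for the difference between female and male bodies with Yohio, and 22 with Ycongo, against 0 with an estimated correlation. Those given here were also called within each sex, in opposite directions. For each list, the median over genes of the difference comes from the fit on 12 libraries. The medians beside it come from the fits on 6 libraries and need not subtract to it. The median difference between XXYohio and XYYohio effects was -1.69 for muscle genes (medians of -1.21 in females and 0.54 in males, adjusted camera p = 8.19e-13 and adjusted p = 0.168 with an estimated correlation). It was -1.31 for cuticle genes (-1.3 and 0.48, adjusted p = 6.73e-07 and adjusted p = 0.144 with an estimated correlation), -0.98 for oxidative phosphorylation genes of the nucleus (-0.65 and 0.33, adjusted p = 5.19e-06 and adjusted p = 0.324 with an estimated correlation) and -0.95 for digestive enzyme genes (-0.65 and 0.37, adjusted p = 7.68e-07 and adjusted p = 0.324 with an estimated correlation). With Ycongo the difference was -1.01 for muscle genes (-0.57 and 0.39, adjusted p = 2.62e-06 and adjusted p = 0.33 with an estimated correlation) and -0.53 for neuronal genes (-0.31 and 0.37, adjusted p = 0.000118 and adjusted p = 0.423 with an estimated correlation).

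The male-body call of each list was lost without at least 1 library. With Yohio in male bodies the adjusted camera p became 0.319 for muscle genes without XY replicate 1 and 0.761 with the direction turned without XYYohio replicate 2, 0.533 for cuticle genes without XYYohio replicate 2, 0.322 and 0.761 for oxidative phosphorylation genes without XY replicate 1 and XYYohio replicate 2, and 0.753 and 0.0878 for digestive enzyme genes without the same libraries. With Ycongo in male bodies it became 0.773, 0.0961 and 0.127 for muscle genes without XY replicate 1, XYYcongo replicate 1 and XYYcongo replicate 2, and 0.862 and 0.388 for neuronal genes without XY replicate 1 and XYYcongo replicate 2. On the female side, the oxidative phosphorylation genes had 0.644 with the direction turned without XX replicate 2 and 0.481 without XXYohio replicate 1, the digestive enzyme genes 0.664 without XX replicate 2, and the neuronal genes with Ycongo 0.141 and 0.465 without XX replicate 1 and XXYcongo replicate 1. No explanation of these differences was tested, a difference in the shares of tissues in whole bodies among them.

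Between female body and ovary, 18 of 34 lists had an adjusted camera p below 0.05 for the difference with Yohio and 13 with Ycongo, against 0 with an estimated correlation. Of these, 2 were also called within each tissue in opposite directions, both with Ycongo. Mitochondrially encoded genes, tRNAs among them, had a median difference of 6.34 (medians of 1.84 in body and -3.91 in ovary, adjusted camera p = 3.24e-16 and adjusted p = 0.578 with an estimated correlation). Ribosomal protein genes had a median difference of -1.0 (-0.51 and 0.36, adjusted p = 1.51e-05 and adjusted p = 0.676 with an estimated correlation). Neither list is firm. The ribosomal list turned direction in the body without XX replicate 2 and in the ovary without XXYcongo replicate 1, and was weaker in the ovary without XX replicate 2. The mitochondrial difference had a fry adjusted p of 0.296, and the mitochondrial share of counts varied as much between body libraries of 1 group as between groups.

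The first pattern weighed was the loss of mitochondrially encoded transcripts from XXYcongo ovaries. Sequence variants of the XXYcongo stock that keep reads from aligning would lower the same transcripts in its other tissues, but their median log2 fold change was -0.13 over 26 genes in the XXYcongo CNS (quartiles -0.42 and 0.06) and 1.84 in the body. Less mitochondria-rich muscle in the ovary samples would lower muscle genes alike, but their median there was -0.03 over 23 genes (quartiles -0.49 and 0.46). In XXYohio ovaries, where the mitochondrially encoded genes had a median of -1.4, muscle genes were lower too (median -0.56, adjusted p = 0.000101 and adjusted p = 0.449 with an estimated correlation), though not without XXYohio replicate 2 (0.0768), so less muscle stays open there. A difference in how poly(A) selection carried mitochondrial RNA, a difference in tissue make-up other than muscle, and an effect of the genotype stay open as untested.

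The second pattern was higher larval cuticle RNA in the XXYohio CNS with lower ImpE2, in a contrast whose 4 calls were matched or exceeded in 9 of 20 data sets simulated without a change. That comparison counts calls and does not weigh single genes. Epidermis or trachea carried along with the CNS would bring chitin and epidermal genes with it, but 11 of 13 such genes lay below 0 with a median of -0.56 (quartiles -1.13 and -0.2), and the median was -0.48 with Ycongo. This speaks only against an admixture large enough to raise these genes, which had 4.3 to 88.5 CPM in XX. Their fall with both added Y chromosomes could also hide a small rise, so a small admixture of epidermis or trachea stays open. Material of other tissues was not tested and stays open, since detoxification genes (median 0.51, adjusted p = 0.00354 and adjusted p = 0.888 with an estimated correlation, 0.54 without XXYohio replicate 2) and lipid and sugar metabolism genes (median 0.26, adjusted p = 0.000576 and adjusted p = 0.615 with an estimated correlation) moved up as well. Sampling of XXYohio larvae at an earlier point of the ecdysone rise remains a candidate explanation of the lower ImpE2: 9 of 10 other ecdysone-inducible genes lay below 0 with a median of -0.54 (quartiles -0.76 and -0.24). The median was -0.52 with Ycongo, where Lcp3 and Lcp4 did not rise, so such timing alone would leave the cuticle genes unexplained. Whether the timing, if it differed, came from sampling or from a slower development of the genotype was not tested.

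The third pattern was FDY reads in XX libraries, which carry no Y: the counts were 3 and 5 in bodies, 32 and 16 in ovaries and 109 and 74 in the CNS. Material of XXY females would have brought 30.0 Suppressor of Stellate counts into both XX ovary libraries together, against 0 observed, and 18.2 and 30.3 into the XX body libraries, against 0 observed. In the CNS, XX replicate 1 held 27 such counts where 103 were expected and replicate 2 held 0 where 70.2 were expected, so a smaller admixture in XX replicate 1 stays open. Reads of the near-identical paralog vig2 assigned to FDY cannot be told apart from other sources for the 6 XX libraries: FDY counts per 100 vig2 counts differed up to 12.6-fold between them, but 3.46-fold when the ends of the counting intervals were compared.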

How the results depend on the processing

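Leaving out mitochondrially encoded genes was the one alternative chosen after the results were seen. For each count of called genes below, the tissue is followed by the values for Yohio, Ycongo and Ycongo against Yohio in that order, where they moved by more than 1.5 times. The cause was not tested except where stated.

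With RLE scaling all 24 counts stayed within 1.5 times. Without a filter on low counts, edgeR called 58, 48 and 17 genes in female bodies, 96, 266 and 163 in ovaries, 264, 90 and 236 in the CNS, and 1, 2 and 1 in testes, and the genes called with both added Y chromosomes numbered 19 in female bodies, 43 in ovaries, 44 in the CNS and 1 in testes. DESeq2 called 14 and 6 with Yohio and Ycongo in female bodies, 23, 185 and 43 in ovaries, 44, 41 and 54 in the CNS, 12 with Ycongo and 16 for Ycongo against Yohio in male bodies, and 4, 6 and 8 in testes. It called 6 genes with both in female bodies, 19 in ovaries, 16 in the CNS and 3 in testes, and 1 and 47 for the difference between female body and ovary. The 16 in male bodies and the 47 come from an adjustment over fewer genes than in edgeR. On the 4 libraries of a contrast alone, the counts were 45 and 6 in ovaries for Yohio and Ycongo, 1, 18 and 1 in the CNS, and 3 and 0 with both in ovaries and CNS. Without mitochondrially encoded genes they were 3 for Ycongo in ovaries, 0 there for Ycongo against Yohio, 2 for Ycongo in the CNS and 2 with both there. Of the 25 ovary calls with Ycongo, 10 were mitochondrially encoded and left out by construction, and 12 of the other 15 fell short of the threshold. Removing called genes raises the adjusted p of genes ranked below them by construction.

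The replicates share only a number between groups, and replicate deviations of 2 groups correlated across genes between -0.44 and 0.57. With replicate number as a block, the counts were 2, 80 and 17 in ovaries, 5 and 9 in the CNS for Ycongo and Ycongo against Yohio, 2 with both in ovaries and 3 with both in the CNS.

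Leaving out each library in turn gave, in the same order, 0 to 46, 2 to 496 and 0 to 198 genes in ovaries and 0 to 110, 0 to 25 and 0 to 185 in the CNS. It gave 0 to 1 with Ycongo and with Ycongo against Yohio in male bodies, 0 to 4 for both in testes, and 0 to 25 and 0 to 4 with both added Y chromosomes in ovaries and CNS. In female bodies, and with Yohio in male bodies and testes, it gave 0 in every case. The number of called lists ranged from 15 to 23, 15 to 22 and 6 to 17 in female bodies, 12 to 13, 7 to 13 and 3 to 8 in ovaries, 5 to 14, 9 to 14 and 7 to 15 in the CNS, 6 to 16, 5 to 12 and 3 to 12 in male bodies, and 4 to 9, 3 to 11 and 3 to 9 in testes. A fit without a library has fewer residual degrees of freedom.

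With a correlation estimated from the data, 0 lists were called in all 15 contrasts, against 20, 20 and 10 in female bodies, 12, 7 and 4 in ovaries, 5, 12 and 15 in the CNS, 8, 9 and 9 in male bodies, and 5, 7 and 5 in testes with the preset one. An estimated correlation above the preset one raises the variance of a list mean by construction. That form of camera also rests on the 3 residual degrees of freedom of a fit, so it can miss a list that moved. Not passing it leaves a list undecided rather than unchanged. Without 1 library, list calls kept direction and threshold in 699 cases, fell short in the same direction in 172 and turned direction in 17, listed here with the range of adjusted p over the 6 libraries left out. Of these, 3 passed in the turned direction: ribosomal protein genes in female bodies with Ycongo without XX replicate 2 (0.0303, 1.72e-10 to 0.0303), mitochondrially encoded genes in female bodies for Ycongo against Yohio (0.00311, 1.05e-23 to 0.211) and neuronal genes in the CNS for the same contrast (0.0043, 7.88e-10 to 0.249), both without XXYohio replicate 2.

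The others turned without passing. In female bodies these were oxidative phosphorylation genes with Yohio without XX replicate 2 (8.61e-12 to 0.644), antimicrobial genes with Yohio without XXYohio replicate 2 (4.23e-09 to 0.763), and, for Ycongo against Yohio, antimicrobial genes without XXYohio replicate 1 (1.94e-18 to 0.697) and proteasome genes without XXYohio replicate 2 (1.5e-06 to 0.519). In ovaries ribosomal protein genes turned with Ycongo without XXYcongo replicate 1 (1.78e-10 to 0.818). In the CNS cell cycle genes turned with Yohio without XXYohio replicate 1 (4.36e-06 to 0.807), and for Ycongo against Yohio ribosomal protein genes (0.594, 1.64e-05 to 0.629) and cell cycle genes (2.88e-05 to 0.467) turned without XXYohio replicate 2. In male bodies sperm structural genes turned with Yohio without XY replicate 1 (0.501, 2.75e-05 to 0.877), muscle genes with Yohio without XYYohio replicate 2 (1.54e-12 to 0.761) and the Stellate and Suppressor of Stellate repeats for Ycongo against Yohio without XYYohio replicate 1 (0.00875 to 0.915). In testes neuronal genes turned with Yohio without XY replicate 2 (1.81e-06 to 0.631) and seminal fluid genes with Ycongo without XY replicate 1 (0.333) and XYYcongo replicate 1 (0.0988, 1.31e-05 to 0.333). The cause was not tested.

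Of 35 results for single genes, all kept direction and call with DESeq2, without the filter and with the block. On the 4 libraries of a contrast 24 fell short of the threshold and 11 kept it, and with RLE 3 fell short and 32 kept it. Without 1 library 108 fell short and 102 kept it, and without mitochondrially encoded genes 12 fell short and 12 kept it. Simulated 4-fold changes were recovered in 7% of cases in female bodies and 16% in male bodies, where the biological coefficient of variation was 0.41 and 0.37, and in 92% in the CNS, where it was 0.24. Library totals did not separate these tissues, with 7742372 to 14013900 counts in female bodies and 7621456 to 10108413 in the CNS.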

Other observations

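The share of counts from the mitochondrial genome ranged from 1.78% to 40.11% over the 30 libraries and differed within groups: it was 33.25% and 5.21% in XXYohio bodies and 10.14% and 40.11% in XYYcongo bodies, against 3.99% to 6.34% in the CNS. Within each group the squared differences between replicates were at least 9.6 times what counting alone gives.

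FDY counts per 100 counts of its paralog vig2 were 0.253 and 0.392 in XX bodies and 5.95 to 11.3 in XXY bodies. They were 1.0 and 0.542 in XX ovaries and 10.5 to 13.0 in XXY ovaries. In the CNS they lay closer together, at 3.18 and 1.67 in XX and 3.61 to 6.07 in XXY. In males they were 6.05 to 10.9 in XY libraries and 16.9 to 32.6 in XYY libraries. Across genes, the log2 fold changes of both added Y chromosomes had a correlation of 0.7 in female bodies, where simulated groups without a change that shared controls gave 0.49, and of 0.54 in ovaries against 0.5, 0.33 in the CNS against 0.5, 0.34 in male bodies against 0.5 and 0.41 in testes against 0.51. The covariances were 0.4 in female bodies against 0.2 simulated, 0.28 in ovaries against 0.12 and 0.16 in the CNS against 0.11. They were 0.1 in male bodies against 0.17 and 0.12 in testes against 0.12. For the CNS the 2 measures thus lay on opposite sides of the simulated values. Genes were drawn independently in the simulated data, whereas whole libraries can shift together. In female bodies, log2 CPM of XXYohio replicate 1 had a correlation of 0.9916 with XXYcongo replicate 2 and 0.9691 with XXYohio replicate 2. A gap from a simulated value therefore does not show an effect shared by both added Y chromosomes.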
